A study of Mus musculus with 20 samples.

How the data were processed

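Livers were frozen in liquid nitrogen, small RNA was enriched with the miRNeasy kit, and libraries were made from 1 µg of RNA with the TruSeq small RNA kit, up to 12 per lane, per the labels' protocols. The deposited files give estimated counts per mature miRNA, which need not be whole, for each of 20 runs. CASAVA is the tool named in the submitters' processing notes. The aligner, the miRBase release, the genome build and the treatment of reads matching several miRNAs are not given in the sources used here, and no coordinates are printed. Some deposited counts are fractional, as they would be if reads were shared between miRNAs, and counts of near-identical miRNAs depend on how that was done. miRNA names were set against the GRCm38.p6 annotation for neighbouring genes. They were also matched to annotated mouse hairpin transcripts for GC content, which was found for 96.4% of the tested miRNAs.

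The 2 runs of a library were summed and rounded to whole numbers, giving 10 libraries. Runs of one library differed little more than sampling allows (chi-square per degree of freedom 1.06 to 1.38), and mice of one genotype far more (85.9 to 1331). The files hold 2 feature lists, of 1399 miRNAs (PiZ mice 1 and 2, WT mice 1 to 3) and 990 miRNAs (PiZ mice 3 to 5, WT mice 4 and 5), so the file set was a term of the model. The 880 miRNAs listed in every file held at least 99.999% of the reads of each file and were used. miRNAs were filtered with filterByExpr, which kept 336, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test, file set and genotype, Benjamini-Hochberg adjustment, threshold 0.05). Standard errors are the fold change divided by the square root of F. CPM are computed from the counts with TMM-scaled library sizes. Lists were tested with camera on log2 CPM (prior count 2), which sets a list against the other miRNAs; fry, also run, tests whether a list moves one way and compares it with no others. Arm balance was tested with limma 3.58.1 on log2 ratios with a pseudocount of 0.5 for hairpins with a mean of 20 or more reads per arm. The miR-122 share was tested with scipy 1.17.1. Alternatives used DESeq2 1.42.0 and sva 3.50.0 in R 4.3.3; plots used matplotlib 3.10.9 in Python 3.11.15.

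The miRNAs named were fixed by rule before the data were examined: the tested members of the miR-34 and miR-449 family, the 12 highest and 12 lowest changed miRNAs with the same sign in both file sets, the 2 most abundant members of each list and the 5 most abundant miRNAs. miR-122 has a comparison of its own. miR-101a-3p, miR-141-3p, both arms of miR-144, miR-200a-3p, miR-216a-5p, miR-217-5p, miR-411-3p, miR-871-3p, the let-7d hairpin and the miRNAs of the closing observations lie outside the rule and were chosen after their values were seen. For a miRNA with 1 to 3 reads in a group, the ratio of group totals is given with a 95% exact binomial counting interval. Reads are not independent molecules, so such intervals cover counting error only and leave out the spread between mice. The replicate numbers of PiZ and WT mice name different animals and pair nothing. The alternatives tried were other scalings, filters and tests, models without the file set term or with a surrogate variable, each run alone, the runs as separate columns, each file set alone and each mouse left out. When the model terms were changed, the tested miRNAs were held at those of the first model; this was settled after seeing that rebuilding the filter also changed which miRNAs were tested, and both versions are given.

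The steps were tested on simulated data drawn from the means, dispersions and library sizes of these 10 libraries. For the comparison of PiZ and WT liver, 7 of 27 tested miRNAs changed 2-fold, 26 of 29 changed 4-fold and 30 of 31 changed 8-fold were recovered, and 1 of 279 unchanged miRNAs was called. With nothing changed, 0 of 357 miRNAs and 0 of 16 lists were called in edgeR and camera. Of 19 hairpins with an 8-fold change of one arm, 19 were called, with 1 unchanged hairpin called among 63 tested. A list shifted 4-fold was called, with 0 others. Each simulated change was given to every PiZ mouse alike, and no difference between file sets was simulated. The recovery rates therefore do not cover a PiZ mouse whose levels lie near those of WT mice. The miRNAs were drawn independently of each other, so lists whose members move together were not tested by this simulation. The estimated correlation in these data was 0.70 for the Dlk1-Dio3 list and 0.72 for the miR-34 and miR-449 list.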

Results

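Small RNA was sequenced from the livers of 6-week-old C57BL/6 mice of 2 genotypes, 5 PiZ mice and 5 wild-type (WT) mice. PiZ mice carry a transgene for the Z variant of human alpha-1 antitrypsin, a secreted protease inhibitor whose Z form is retained in the endoplasmic reticulum of hepatocytes. Each library was sequenced in 2 technical runs, which were summed, so that the mouse is the replicate. Summed totals ranged from 1307849 reads in WT mouse 1 to 10780704 reads in PiZ mouse 4. The totals were 2433272, 2507509, 9219121, 10780704 and 9775060 reads for PiZ mice 1 to 5, and 1307849, 2041669, 1524417, 7043887 and 10012738 reads for WT mice 1 to 5. A single read was worth 0.715 CPM (reads scaled to a library of 1000000 reads) in the shallowest library and 0.0887 CPM in the deepest, so miRNAs of a few CPM were measured with little precision in WT mice 1 and 3. The transgene's own mRNA is not measured by these libraries, so the genotype rests on the labels. The sex of the mice is not given in the sources used here.

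A single miRNA, miR-22-3p, made up 38.5% to 59.7% of the reads of a library. The next most abundant were miR-192-5p at 151650.1 ± 45400.5 CPM in PiZ and 137198 ± 78339 CPM in WT liver (SD, n = 5 each), miR-148a-3p at 106039.8 ± 31239 CPM in PiZ and 55806 ± 19402 CPM in WT liver (SD, n = 5 each) and miR-26a-5p at 44802 ± 5712 CPM in PiZ and 60560.4 ± 1553 CPM in WT liver (SD, n = 5 each). None of these 4 passed the test between genotypes (miR-22-3p log2 fold change -0.11, adjusted p = 0.743; miR-192-5p 0.10, adjusted p = 0.922; miR-148a-3p 0.92, adjusted p = 0.0947; miR-26a-5p -0.44, adjusted p = 0.116; edgeR). The first principal component of log2 CPM held 61.8% of the variance and parted PiZ mice 1 to 4 from all WT mice. PiZ mouse 5 lay with the WT libraries on it, and the library it correlated with best was WT mouse 5 (r = 0.985 over 336 miRNAs, which are not independent replicates). WT mice 1 and 3 had the highest values on the second component (10.8 and 8.07), which held 15.6%. PiZ mice 1 to 4 lay between 0.681 and 4.18 on it, and PiZ mouse 5 and WT mice 2, 4 and 5 between -7.43 and -5.62.

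**Figure D1:**
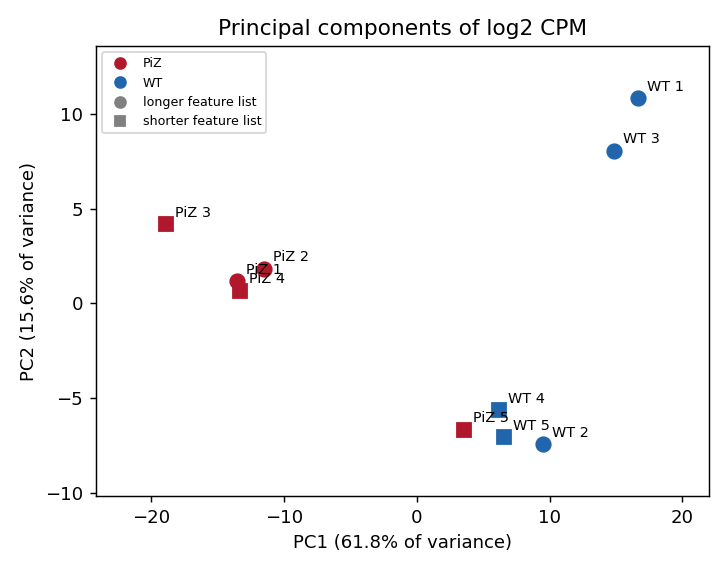
Principal components of log2 CPM for the 10 livers, 1 point per mouse, with genotype as colour and the feature list of the deposited files as shape. PiZ mice 1 to 4 lie between -18.9 and -11.5 on the first component, and PiZ mouse 5 lies at 3.54, on the side of the WT mice.

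The first comparison asked which miRNAs differ between PiZ and WT liver. miR-34b and miR-34c, miR-216b, miR-708 and miR-6364 were higher in PiZ liver, together with a group of miRNAs of the imprinted Dlk1-Dio3 cluster. miR-34c-5p was the most abundant of these, at 3253 ± 1945 CPM in PiZ and 22.1 ± 9.59 CPM in WT liver (SD, n = 5 each). miR-6364, a miRNA encoded near Nagpa in the GRCm38.p6 annotation, had the smallest p, at 51.3 ± 24.1 CPM in PiZ and 2.10 ± 0.730 CPM in WT liver (SD, n = 5 each) (log2 fold change 4.55, SE 0.48, adjusted p = 4.50e-04, 5 of 5 PiZ mice above all WT mice). 3 miRNAs were lower, miR-1948-3p, miR-30c-1-3p and miR-871-3p. Of 336 miRNAs tested, 31 passed a Benjamini-Hochberg adjusted p of 0.05 in edgeR's quasi-likelihood test, 28 higher and 3 lower in PiZ, and 82 had an unadjusted p under 0.05.

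**Figure D2:**
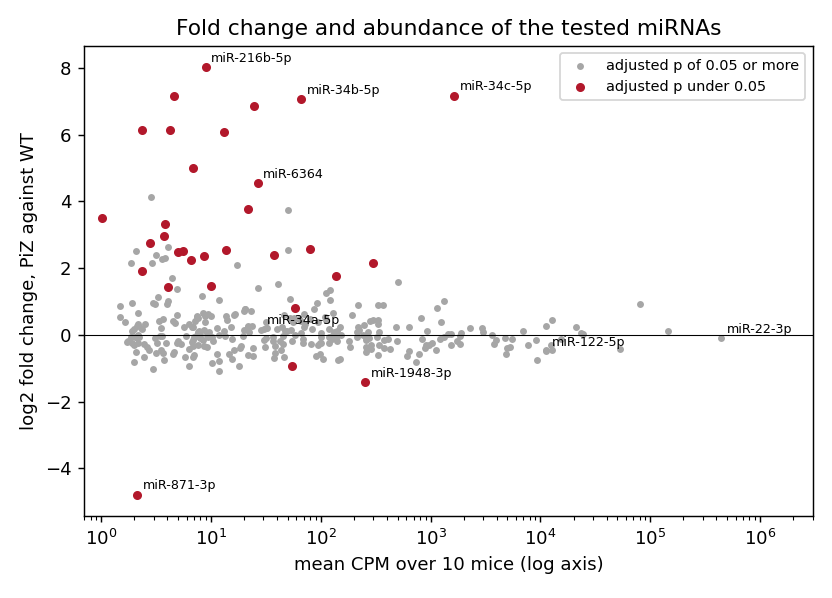
Log2 fold change of PiZ against WT for each tested miRNA (vertical axis) over its mean CPM in the 10 mice (horizontal log axis); red points have an adjusted p under 0.05 (edgeR). miR-34c-5p lies at 7.17 with a mean of 1637 CPM, while miR-34a-5p lies at 0.15. Fitted values of miRNAs with 1 to 3 reads in a group depend on the prior count.

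miR-216b-5p and miR-217-5p are encoded together and are known as pancreas miRNAs. The PiZ to WT ratio of miR-216b-5p was 390.5 (95% counting interval 69.8 to 15446; 646 PiZ and 1 WT reads), and that of miR-217-5p, named here after its values were seen, was 111 (95% counting interval 19.6 to 4392; 183 PiZ and 1 WT reads). Both arms of miR-708, which lies in an intron of Tenm4 and is known to be induced by the unfolded protein response, were higher. miR-708-3p stood at 13.4 ± 6.97 CPM in PiZ and 0.381 ± 0.262 CPM in WT liver (SD, n = 5 each) (log2 fold change 4.99, SE 0.80, adjusted p = 0.00303, 5 of 5 PiZ mice above all WT mice), and the ratio of miR-708-5p was 226 (95% counting interval 40.3 to 8952; 374 PiZ and 1 WT reads). miR-1948-3p, encoded within Ttc39c, fell from 371 ± 70.7 CPM in WT to 139 ± 76.5 CPM in PiZ liver (SD, n = 5 each; log2 fold change -1.42, SE 0.35, adjusted p = 0.0318, 5 of 5 PiZ mice below all WT mice). miR-30c-1-3p fell from 69.4 ± 16 to 38.8 ± 13.0 CPM (log2 fold change -0.94, SE 0.26, adjusted p = 0.0417, 4 of 5 PiZ mice below all WT mice). miR-871-3p, of an X-linked cluster and outside the fixed naming rule, had a ratio of 0.0224 (95% counting interval 0.00264 to 0.0849; 2 PiZ and 54 WT reads).

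**Figure D3:**
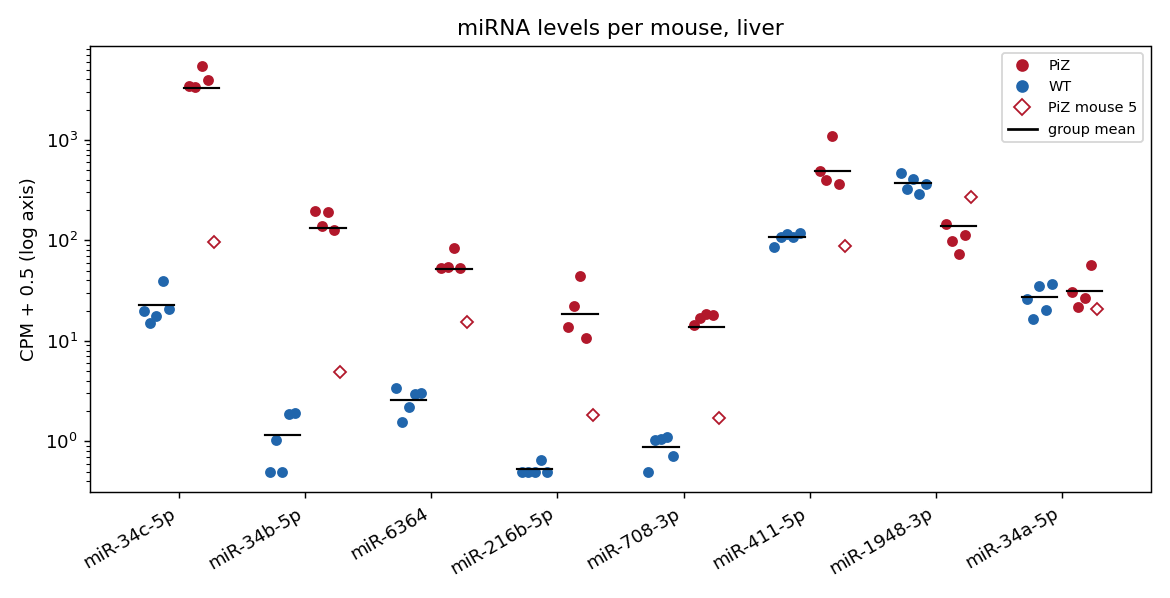
CPM + 0.5 on a log axis of selected miRNAs, 1 point per mouse, with the group mean as a bar and PiZ mouse 5 as an open diamond. For miR-34c-5p, PiZ mice 1 to 4 lie between 3396 and 5409 CPM, PiZ mouse 5 at 95.8 CPM and the WT mice between 14.6 and 38.8 CPM.

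PiZ mouse 5 differed from the other PiZ mice in most of these miRNAs. PiZ mice 1 to 4 all lay above all WT mice for 26 of the 28 higher miRNAs, and PiZ mouse 5 did so for 12. These miRNAs were selected by a fit to the same mice, so the counts describe the mice and test nothing. In PiZ mouse 5, miR-6364 was 15.1 CPM, between the 52.4 to 82.8 CPM of the other PiZ mice and the 1.04 to 2.86 CPM of the WT mice. The count of 31 changed miRNAs moved with each mouse. Left out one at a time with the filter rebuilt, PiZ mice 1 to 4 left 9, 12, 17 and 20 changed miRNAs, PiZ mouse 5 left 46, and WT mice 1 to 5 left 12, 10, 12, 5 and 8; with the tested miRNAs held the range was 8 to 53. Without WT mice 1 and 3, a choice made after seeing the data, 0 passed in edgeR and 104 had an unadjusted p under 0.05; with PiZ mouse 5 left out as well, 100 passed. limma-voom called 7 miRNAs and DESeq2 50.

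**Figure D4:**
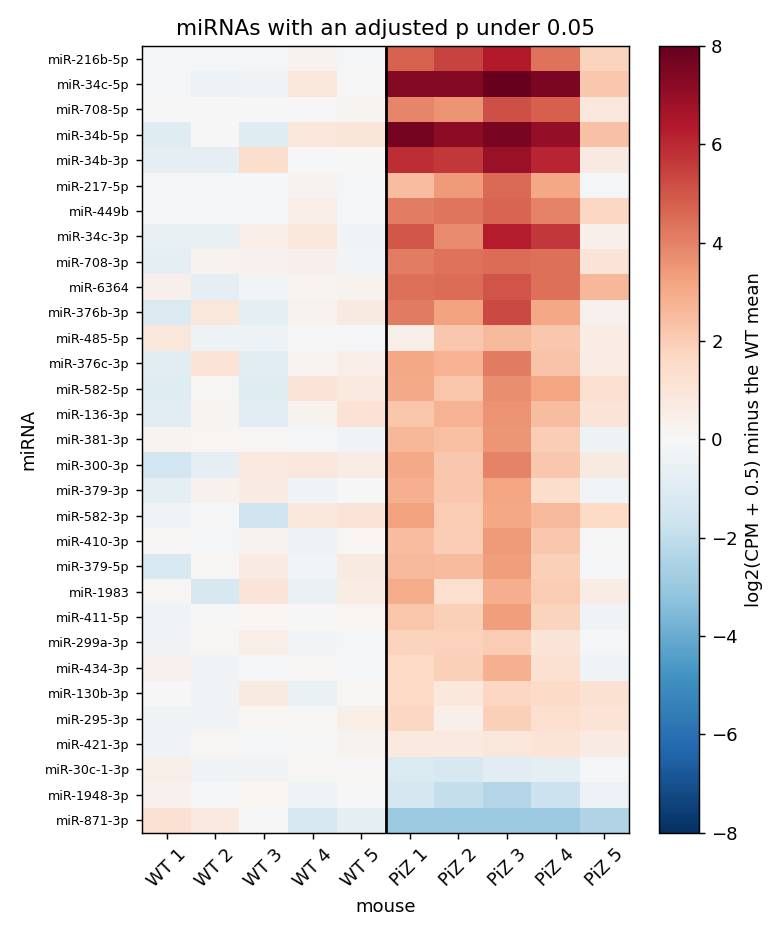
Log2(CPM + 0.5) minus the WT mean for the miRNAs with an adjusted p under 0.05, 1 column per mouse and 1 row per miRNA, ordered by fitted fold change. The column of PiZ mouse 5 is paler than those of PiZ mice 1 to 4, and the lowest 3 rows are the miRNAs lower in PiZ.

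The second comparison concerned the miR-34 and miR-449 family, whose members respond to p53 and cell stress. 5 of its 6 tested members rose in PiZ liver, and 5 did so when adjusted over the list alone. miR-34c-5p (log2 fold change 7.17, SE 0.90, adjusted p = 0.00119, 5 of 5 PiZ mice above all WT mice), miR-34b-5p (log2 fold change 7.07, SE 1.01, adjusted p = 0.00247, 5 of 5 PiZ mice above all WT mice), miR-34b-3p (log2 fold change 6.85, SE 1.19, adjusted p = 0.00490, 4 of 5 PiZ mice above all WT mice) and miR-34c-3p (log2 fold change 6.07, SE 1.23, adjusted p = 0.0151, 4 of 5 PiZ mice above all WT mice) come from adjacent hairpins. miR-34b-5p stood at 132 ± 77.9 CPM in PiZ and 0.659 ± 0.698 CPM in WT liver (SD, n = 5 each). The ratio of miR-449b was 86.1 (95% counting interval 23.6 to 715; 285 PiZ and 2 WT reads). Members of the family share a seed, and reads of such similar miRNAs can be split between them by the counting, so miR-449b is uncertain. miR-34a-5p, encoded elsewhere in the genome, was 30.9 ± 14.9 CPM in PiZ and 26.6 ± 8.83 CPM in WT liver (SD, n = 5 each) (log2 fold change 0.15, SE 0.35, adjusted p = 0.837). PiZ mouse 5 had 4.42 CPM of miR-34b-5p, against 127 to 197 CPM in PiZ mice 1 to 4 and at most 1.41 CPM in WT mice. As a set the family ranked above the other miRNAs in camera with a preset correlation of 0.01 (adjusted p = 1.21e-04), which was lost with an estimated correlation (adjusted p = 0.478). Against no change, without regard to other miRNAs, the family had an adjusted p of 0.0105 in fry. The count of changed members fell to 2 when WT mouse 4 was left out and the filter rebuilt (4 with the tested miRNAs held), with limma-voom and with 1 surrogate variable, and to 0 without WT mice 1 and 3 and in the shorter-list file set alone. In that set the arms of miR-34b and miR-34c had log2 fold changes of 6.06 to 7.31 without passing. In the longer-list file set alone, these arms and miR-449b passed (adjusted p of 9.62e-06 to 0.00895, edgeR).

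The third comparison covered lists of miRNAs fixed before the data were examined. The Dlk1-Dio3 cluster, an imprinted region whose miRNAs are expressed from the maternal allele, had 23 tested members. 12 rose, 22 did so when adjusted over the list alone, and all 23 had a positive log2 fold change (median 2.39, or 2.38 with 1 member of 3 or fewer WT reads at its lower counting bound), under each scaling tried. The members lie in 1 region, include both arms of hairpins such as miR-411 and move together (estimated correlation 0.70), so these counts are not of independent miRNAs. miR-411-5p rose from 106 ± 12.9 to 486 ± 369 CPM (SD, n = 5 each; log2 fold change 2.15, SE 0.52, adjusted p = 0.0297, 4 of 5 PiZ mice above all WT mice), and miR-381-3p from 23.9 ± 3.66 to 135 ± 95.9 CPM (log2 fold change 2.56, SE 0.56, adjusted p = 0.0187, 4 of 5 PiZ mice above all WT mice). miR-376b-3p (log2 fold change 3.78, adjusted p = 0.0187) and miR-376c-3p (log2 fold change 3.34, adjusted p = 0.0318) also rose. miR-127-3p, the most abundant member, had a log2 fold change of 1.57 (adjusted p = 0.109) and did not pass. The median log2 ratio to the WT mean was 1.99, 1.97, 3.20 and 1.77 in PiZ mice 1 to 4 and -0.27 in PiZ mouse 5. Against the other miRNAs, the adjusted p was 1.31e-08 in camera with the preset correlation and 0.478 with an estimated correlation. fry asks another question, whether members move one way on balance without regard to other miRNAs, and its adjusted p was 0.0604.

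No other list passed in camera with the preset correlation. Of 4 tested members of the muscle and pancreas list, miR-216b-5p and miR-217-5p rose, while miR-216a-5p (4.12, adjusted p = 0.0579) and miR-375-3p (-0.077, adjusted p = 0.932) did not pass (list adjusted p = 0.0763). All 4 are known as pancreas miRNAs, and no muscle member of the list passed the filter, so the list says nothing of muscle. The muscle and pancreas list passed when PiZ mouse 1, 2 or 5 or WT mouse 1 or 3 was left out, all with the preset correlation; with an estimated correlation (0.59) its adjusted p over all mice was 0.569. The unfolded protein response list had both arms of miR-708 higher and miR-30c-1-3p lower among 8 tested members (adjusted p = 0.653 against the other miRNAs in camera, and 0.010 against no change in fry). miR-30c-2-3p, also in this list, had a log2 fold change of -0.37 (adjusted p = 0.411, edgeR) and did not pass. Only 4 of the 8 list members had a positive log2 fold change. The median was 0.22 and the mean 1.45, raised by the arms of miR-708, which are 1 hairpin. Whether the fry result holds without that hairpin was not tested. The biliary-epithelial list had 6 of 6 members with a positive log2 fold change and none past 0.05 over all miRNAs, 2 when adjusted over the list alone (adjusted p = 0.184 against the other miRNAs in camera, and 0.010 against no change in fry). The 2 that passed, miR-141-3p and miR-200a-3p, had near-identical counts, so they can be 1 signal counted under both names, which also enters the count of 6 and the fry p. In the erythroid list (adjusted p = 0.208 in camera), miR-451a had a log2 fold change of 1.27 (adjusted p = 0.119), and 3 of 4 members passed when adjusted over the list alone. These were miR-451a and both arms of the miR-144 hairpin, so the 3 are not independent. The other member, miR-486-5p, had a log2 fold change of 0.25 (adjusted p = 0.816, edgeR).

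Lists of other cell types had no member past 0.05. These were the immune list, with a list adjusted p of 0.242 (miR-142-5p log2 fold change 1.03, adjusted p = 0.216), the mesenchymal list, with 0.742 (miR-143-3p 0.27, adjusted p = 0.605), and the 2 endothelial miR-126a arms, too few for a list test (miR-126a-5p 0.064, adjusted p = 0.948; miR-126a-3p 0.084, adjusted p = 0.892). The hepatocyte-enriched list gave an adjusted p of 0.809, with a positive median (0.10) and mean (0.21) but a negative direction in camera. Adjusted p was 0.0763 for lipid and glucose metabolism (miR-378a-3p -0.39, adjusted p = 0.327), 0.208 for miR-17/92 and paralogs (miR-93-5p -0.14, adjusted p = 0.732), 0.338 for the miR-15, miR-16 and miR-195 list (miR-16-5p -0.31, adjusted p = 0.515), 0.338 for let-7 (let-7f-5p 0.22, adjusted p = 0.643), 0.338 for the cluster of miR-183, miR-96 and miR-182 (miR-182-5p 0.90, adjusted p = 0.186), 0.483 for injury and regeneration (miR-21a-5p 0.039, adjusted p = 0.971) and 0.765 for miR-29 (miR-29a-3p -0.14, adjusted p = 0.743). No Igf2/H19 member passed the filter. The signs of the log2 fold changes of miR-21a-5p, miR-192-5p, miR-126a-5p, miR-126a-3p, miR-15b-5p and miR-29b-3p flipped under some scalings.

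The fourth comparison was of miR-122, the main hepatocyte miRNA, which can take most of the counts of a liver library. It took far less here, for a reason not tested, so shares of reads need not be shares of molecules in the liver. Its share of all miRNA reads was 0.955% ± 0.172 in PiZ and 1.31% ± 0.139 in WT liver (SD, n = 5 each), a PiZ minus WT difference of -0.359 percentage points (exact two-sided permutation test, p = 0.0159). Within the 2 sets of files, the difference was -0.410 points among 2 PiZ and 3 WT mice (exact p = 0.400) and -0.317 points among 3 PiZ and 2 WT mice (exact p = 0.200), groups too small to reach 0.05. Without WT mice 1 and 3 it was -0.280 points (exact p = 0.0714). miR-122-5p as a single miRNA had a log2 fold change of -0.48 (adjusted p = 0.119) in edgeR and did not pass. The share of miR-22-3p was 42.5% ± 3.20 in PiZ and 46.5% ± 9.04 in WT liver (exact permutation p = 0.413).

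The fifth comparison asked whether the balance of the 5p and 3p arms of a hairpin differs between genotypes. For let-7d, the log2 ratio of 5p to 3p reads was 1.35 in PiZ and 0.86 in WT liver, a fitted difference of 0.51, SE 0.19 (adjusted p = 0.514, limma). The hairpin of miR-34c had the smallest p (adjusted p = 0.475), but miR-34c-3p had 8 reads over the 5 WT mice and 0 in WT mice 1 and 2, so its WT ratio depends on the pseudocount and no difference is given. 0 of 64 hairpins passed in limma, and 3 had an unadjusted p under 0.05. miR-34c and miR-411, with few WT reads of the 3p arm (26 for miR-411-3p), passed with a pseudocount of 5, and miR-34c without WT mouse 5, calls that rest on the same low counts.

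The last comparison asked whether the genotype effect differs between the 2 sets of files. miR-34c-5p had a difference of log2 fold changes of -0.96 (SE 1.49, adjusted p = 0.905, edgeR) and miR-411-5p one of 0.020 (SE 1.06, adjusted p = 0.993). 0 of 372 miRNAs passed in edgeR, 16 had an unadjusted p under 0.05, and DESeq2 called 0. With SEs of this size, the lack of calls does not show that the effects are equal in the 2 sets. Without WT mouse 2, 15 passed, among them miR-21a-5p, let-7f-5p and miR-101a-3p. The WT mice of the longer list are then WT mice 1 and 3 alone, with 6129 and 9172 CPM of miR-21a-5p against 32024 to 35949 CPM in the other WT mice, so these calls rest on those 2 libraries.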

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

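The tests of PiZ mouse 5 and of pancreas tissue, the count on the smaller side of splits and the split not drawn were chosen after the values were seen; those of WT mice 1 and 3 and the remaining counts of splits were set before they were run. 19 gaps among 98 groups of 5 mice passed Dixon's limit of 0.71, where chance gives about 4.90 for normal values in independent groups. The groups here share mice, hold related miRNAs and in part values of 0, so the 19 are not independent departures. PiZ mouse 5 gave 9 of the 19. Its gap to the nearest PiZ mouse, as a share of the group's range on the log2 scale, is given for miR-6364 (0.729), miR-34c-5p (0.884), miR-34b-5p (0.883), miR-449b (0.772), miR-708-3p (0.899), miR-34b-3p (0.798), miR-143-3p (0.748), where it was lowest, and for miR-378a-3p (0.763), miR-30c-2-3p (0.719), where it was highest. WT mouse 1 was highest for miR-378d (0.747), miR-378a-3p (0.857), miR-30c-2-3p (0.732), miR-22-3p (0.758). Single gaps were seen for miR-142-5p (0.877) in PiZ mouse 2, miR-146a-5p (0.765) in WT mouse 3 and miR-183-5p (0.799) in WT mouse 5. A gap of 1, for miR-449b and miR-216b-5p in WT mouse 4 and miR-708-5p in WT mouse 5, comes from 1 or 2 reads where the other WT mice had 0.

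PiZ mouse 5 lay with the WT libraries. If its library came from a WT liver, its median log2 ratio on the miRNAs higher in the other 4 PiZ mice should lie within those of WT libraries held out in turn. It was 0.35 over 45 miRNAs, against -0.31 to 0.18, above all 5 but by less than their range, so a wrong label stays open. Carry-over of PiZ reads into a WT library at one share, at most 3.02% from miR-34c-5p, left 5 miRNAs above what that share could give, but held-out WT libraries gave up to 4, and the margin over them was set after both were seen, so carry-over cannot be told apart from the spread of WT mice. miR-6364, at a lower 95% counting limit of 12.6 CPM against a limit of 5.36 CPM, was the farthest above. A PiZ mouse with a weaker response was not tested, since the labels give no second measure of the transgene.

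WT mice 1 and 3 had the highest values on the second component and were the shallowest. The gap on this component was taken between their mean and the mean of all other libraries, which are not 1 group there. With all libraries thinned to 1307557 reads, that gap kept 0.929 of its size (0.884 to 0.979 over 20 draws), which argues against depth. A base composition trend over hairpins may contribute: the difference of WT mice 1 and 3 from the other WT libraries correlated with hairpin GC content (Spearman rho 0.44 across miRNAs, which are not independent). The split of WT mice 2 and 4 from the rest gave -0.443, of nearly the same size, but that split is close to a mirror image of this one. The design gives no biological explanation for it, and none was tested.

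miR-216b-5p and miR-217-5p were higher in PiZ. Pancreas tissue in the PiZ livers may bring them, and would also bring miR-375-3p, whose log2 fold change had an upper 95% limit of 0.80, below the size of 1 first set to argue against pancreas. A condition on its baseline was added after the values were seen, and its outcome depends on the miRNA chosen: the WT level of miR-375-3p, 10.2 CPM, lies above the PiZ mean of miR-217-5p, 4.70 CPM, but below that of miR-216b-5p, 17.9 CPM. PiZ mouse 3 had the most miR-216b-5p, 43.2 CPM. Its miR-375-3p, 14.8 CPM, was the highest of the PiZ mice (from 3.68 CPM) but within the 5.22 to 15 CPM of the WT mice. How much miR-375-3p pancreas would bring for each read of miR-216b-5p is not measured here. These values therefore do not decide, and this explanation cannot be told apart from a change in liver cells.

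Other splits of the 10 libraries into 5 and 5 were fitted, 100 of 126, the real one included here and in each count below; 1 equals the file sets and could not be fitted with the file set term. For the count of changed miRNAs, 4 drawn splits gave at least the real 31 (highest other 64). The split of PiZ mice 1 to 4 with WT mouse 1 was not drawn; fitted by itself it gave 41 changed miRNAs and 5 of the family, so whether chance is excluded depends on the draw and is left undecided. All fitted splits near or above the real count put PiZ mice 1 to 4 together with 1 WT mouse, which points to a structure of the samples carried by those 4 mice. Apart from these and the real split, no drawn split gave more than 2 changed miRNAs. For the 28 higher miRNAs, 5 splits gave as many on their larger side (highest other 47). Those 5 all hold PiZ mice 1 to 4 together and share most of the real grouping, so this count cannot decide on chance. For the 3 lower it is left undecided: 5 splits reach it on their larger side (highest other 47) but 4 on their smaller side, the like comparison (highest other 17), and these counts fall on either side of the limit of 5. For the family's 5 members, 4 drawn splits gave as many (highest other 5), and the split not drawn did too, so this is undecided as well. For the 2 lists chance is not excluded: 44 splits called as many, and the highest other called 6. For arm balance all 100 splits reach the real 0, and the highest other gave 6.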

How the results depend on the processing

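The settings without WT mice 1 and 3, without those and PiZ mouse 5, and with a filter rebuilt or held were chosen after seeing the data. The 15 changed miRNAs named by the rule kept their sign under every alternative that tested them, but their calls did not: miR-34c-5p and miR-6364 lost theirs in 2 of 28 alternatives each, and miR-30c-1-3p in 16. The count of 31 changed miRNAs (28 higher, 3 lower, 5 of the family) became 28 (22 higher, 6 lower, 5 of the family) with upper-quartile factors; 83 (71 higher, 12 lower, 5 of the family) with no filter beyond 1 count; 13 (11 higher, 2 lower, 4 of the family) with mean CPM of 10 or more; 50 (39 higher, 11 lower, 5 of the family) with DESeq2; 7 (5 higher, 2 lower, 2 of the family) with limma-voom; 6 (4 higher, 2 lower, 2 of the family) with 1 surrogate variable; 17 (16 higher, 1 lower, 2 of the family) with no file set term, filter rebuilt; 4 (2 higher, 2 lower, 1 of the family) with 1 surrogate variable, filter rebuilt; 21 (20 higher, 1 lower, 5 of the family) with first run only; 18 (17 higher, 1 lower, 5 of the family) with second run only; 27 (18 higher, 9 lower, 2 of the family) with the 20 runs with the mouse as a random effect and the run number as a replicate block; 28 (25 higher, 3 lower, 3 of the family) with arms summed; 0 (0 higher, 0 lower, 0 of the family) with shorter-list file set alone; 0 (0 higher, 0 lower, 0 of the family) without WT mice 1 and 3; 100 (68 higher, 32 lower, 5 of the family) without PiZ mouse 5 and WT mice 1 and 3. Of the miRNAs called with the replicate block, 12 were among the 31. The longer-list file set alone called 22 (20 higher, 2 lower), of which 20 were among the 31. A median over all tested miRNAs moved by -0.16 (log2) with upper-quartile factors and by -0.12 with TMM without miR-122. Rebuilding the filter changes how many miRNAs are tested, 300 in place of 336 without the file set term; with the tested miRNAs held, that model called 36. The cause of the other differences was not tested.

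Leaving out 1 mouse gave 5 to 46 changed miRNAs with the filter rebuilt and 8 to 53 with it held, 4 to 41 and 7 to 45 higher, 0 to 5 and 1 to 8 lower, and 2 to 5 and 4 to 5 of the family. Counts that moved by more than 1.5 times, with the filter rebuilt, were, for lower miRNAs, 1 without PiZ mouse 1, 0 without PiZ mouse 3, 0 without PiZ mouse 4, 5 without PiZ mouse 5, 1 without WT mouse 3, 1 without WT mouse 4, 1 without WT mouse 5; and for higher miRNAs, 8 without PiZ mouse 1, 10 without PiZ mouse 2, 17 without PiZ mouse 3, 8 without WT mouse 1, 8 without WT mouse 2, 11 without WT mouse 3, 4 without WT mouse 4, 7 without WT mouse 5. The family count was 2 without WT mouse 4 (4 with the filter held), and the effect of 15 miRNAs differed between file sets without WT mouse 2, calls that rest on WT mice 1 and 3. It gave 2 to 4 lists, the most without PiZ mouse 2 and without WT mouse 3, where the muscle and pancreas list and the lipid and glucose metabolism list passed as well, 0 to 1 hairpins and 0 to 15 miRNAs whose effect differs between file sets. Lists passing numbered 0 with an estimated correlation, 4 without a filter, 4 without WT mice 1 and 3 and 5 without those and PiZ mouse 5. With fry they numbered 3, the miR-34 and miR-449 family, biliary-epithelial and unfolded protein response lists, without the Dlk1-Dio3 cluster. With a pseudocount of 5, 2 hairpins passed, and with no filter 6 miRNAs differed in effect between file sets. Among them were miR-133a-3p, miR-133c and miR-9-5p, each at least 10 times as high in PiZ mouse 4 as in any other mouse. The miR-122 share difference, -0.359 points, was -0.410 and -0.317 points in the file sets alone and -0.280 points without WT mice 1 and 3, and kept its sign under all alternatives tried.

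Of the 31 changed miRNAs, 0 turned sign under the alternatives that tested them, summed arms left aside. Among the other miRNAs named by the rule, some did. Their log2 fold changes became miR-21a-5p -0.00720 with RLE size factors. They became miR-29b-3p -0.096, miR-126a-3p -0.078, miR-15b-5p -0.059, miR-192-5p -0.060, miR-126a-5p -0.099, miR-21a-5p -0.12 with upper-quartile factors. They became miR-29b-3p -0.049, miR-126a-3p -0.050, miR-15b-5p -0.00299, miR-192-5p -0.033, miR-126a-5p -0.081, miR-21a-5p -0.093 with TMM without miR-122. They became miR-29b-3p -0.035, miR-126a-3p -0.016, miR-192-5p -0.032, miR-126a-5p -0.058, miR-21a-5p -0.097 with no filter beyond 1 count. They became miR-21a-5p -0.00720 with DESeq2. They became miR-146a-5p 0.034 with limma-voom. They became miR-375-3p 0.018 with no file set term. They became let-7a-5p 0.073, miR-181a-5p 0.062, miR-143-3p -0.26, let-7f-5p -0.33, miR-93-5p 0.12, miR-29a-3p 0.20, miR-22-3p 0.025, miR-126a-3p -0.35, miR-192-5p -0.50, miR-146a-5p 0.52, miR-375-3p 0.14, miR-126a-5p -0.70, miR-21a-5p -0.70 with 1 surrogate variable. They became miR-375-3p 0.00906 with second run only. They became miR-146a-5p 0.093, miR-375-3p 0.11 with the 20 runs with the mouse as a random effect and the run number as a replicate block. They became miR-30c-5p 0.00495, miR-200c-3p -0.032, miR-486-5p -0.21, miR-34a-5p -0.00308, miR-15b-5p -0.58 with longer-list file set alone. They became miR-143-3p -0.31, let-7f-5p -0.34, miR-93-5p 0.047, miR-29a-3p 0.077, miR-126a-3p -0.18, miR-192-5p -0.28, miR-146a-5p 0.62, miR-375-3p 0.065, miR-126a-5p -0.32, miR-21a-5p -0.45 with shorter-list file set alone. They became miR-143-3p -0.11, let-7f-5p -0.15, miR-29a-3p 0.043, miR-126a-3p -0.23, miR-192-5p -0.41, miR-146a-5p 0.43, miR-375-3p 0.18, miR-126a-5p -0.46, miR-21a-5p -0.52 without WT mice 1 and 3. They became let-7f-5p -0.13, miR-126a-3p -0.097, miR-192-5p -0.60, miR-146a-5p 0.61, miR-375-3p 0.25, miR-126a-5p -0.41, miR-21a-5p -0.66 without PiZ mouse 5 and WT mice 1 and 3. Of these, miR-192-5p, miR-126a-5p and miR-21a-5p passed with the new sign in the last setting. Over the mice left out, log2 fold changes whose sign turned ranged -0.17 to 0.33 for let-7f-5p, -0.24 to 0.24 for miR-126a-3p, -0.31 to 0.47 for miR-126a-5p, -0.062 to 0.45 for miR-143-3p, -0.46 to 0.46 for miR-146a-5p, -0.21 to 0.16 for miR-15b-5p, -0.076 to 0.81 for miR-183-5p, -0.22 to 0.45 for miR-192-5p, -0.041 to 0.34 for miR-200c-3p, -0.46 to 0.42 for miR-21a-5p, -0.16 to 0.086 for miR-29b-3p, -0.17 to 0.74 for miR-486-5p, -0.13 to 0.31 for miR-34a-5p, -0.56 to 0.068 for miR-375-3p.

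The direction of the hepatocyte-enriched list differed in fry, which tests against no change (adjusted p = 0.652) and turned with no filter (adjusted p = 0.897), and directions turned for hepatocyte-enriched (adjusted p 0.663 to 0.992), mesenchymal (adjusted p 0.522 to 0.978), miR-29 family (adjusted p 0.604 to 0.901) when 1 mouse was left out. Low depth limits miRNAs of a few CPM, which 1 read can move in WT mice 1 and 3.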

Other observations

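Changed miRNAs outside the fixed lists and the naming rule are named here after their values were seen; miR-871-3p, also among them, had 2 PiZ and 54 WT reads. Both arms of miR-582, encoded within Pde4d, were higher in PiZ (miR-582-5p 2.96, adjusted p = 0.0187 and miR-582-3p 2.49, adjusted p = 0.0187 as log2 fold changes, edgeR). miR-130b-3p, encoded beside Sdf2l1, was 14.4 ± 3.19 CPM in PiZ and 5.43 ± 2.12 CPM in WT liver (SD, n = 5 each) (log2 fold change 1.45, SE 0.32, adjusted p = 0.0187, 5 of 5 PiZ mice above all WT mice). miR-421-3p, encoded within Ftx, was 74.6 ± 8.49 CPM in PiZ and 42.0 ± 6.69 CPM in WT liver (SD, n = 5 each) (log2 fold change 0.79, SE 0.19, adjusted p = 0.0297, 5 of 5 PiZ mice above all WT mice). For these last 2 miRNAs PiZ mouse 5 lay above all WT mice, at 12.9 and 65.9 CPM. miR-295-3p (log2 fold change 1.42, adjusted p = 0.0318) and miR-1983, encoded among tRNA genes (log2 fold change 2.23, adjusted p = 0.0417), were also higher.

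PiZ mouse 4 held miRNAs known from other tissues, a pattern looked for after values were seen. Over the miRNAs listed in every file, 8 had at least 10 times the CPM of every other mouse, with 20 reads or more, in PiZ mouse 4, and 0 did so in each of the other 9 mice. Of these, miR-133c, miR-133a-3p and miR-1a-3p are known from muscle: miR-133c at 455 CPM (at most 11.7 CPM in any other mouse), miR-133a-3p at 41.3 CPM (at most 2.15 CPM in any other mouse) and miR-1a-3p at 25.4 CPM (at most 1.04 CPM in any other mouse). The others are known from brain or nerve: miR-9-5p at 59.6 CPM (at most 2.20 CPM in any other mouse), miR-204-5p at 11 CPM (at most 0.818 CPM in any other mouse), miR-219a-2-3p at 7.72 CPM (at most 0.303 CPM in any other mouse), miR-124-3p at 6.66 CPM (at most 0.303 CPM in any other mouse) and miR-153-3p at 2.40 CPM (at most 0.217 CPM in any other mouse). Both runs of the library held them, with 2596 and 2527 reads of miR-133c. Where they came from was not tested. Apart from PiZ mouse 4, miR-133c was low but still above all WT mice in each PiZ mouse, and it did not pass (log2 fold change 3.73, adjusted p = 0.159, edgeR). When PiZ mouse 4 was left out, 20 miRNAs were changed, 5 of them in the miR-34 and miR-449 family.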
